A study of Bifidobacterium adolescentis and Bifidobacterium adolescentis
Bifidobacterium longum subsp. infantis ATCC 15697 = JCM 1222 = DSM 20088
Bifidobacterium bifidum PRL2010
Bifidobacterium breve 12L and Bifidobacterium adolescentis
Bifidobacterium bifidum PRL2010 with 5 samples.

How the data were processed

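RNA of Bifidobacterium adolescentis 22L was measured on 2-colour Agilent arrays. Per the labels, the array was designed on 4 bifidobacterial genomes, those of the studied strain and of B. longum subsp. infantis ATCC15697 (B. infantis below), B. breve 12L and B. bifidum PRL2010, with 60-base probes and about 5 probes per gene. The series had 5 samples, each a comparison of 2 RNAs and each on 2 arrays, called array I and array II here. Each sample was its own group with n = 1. Per the labels, mouse RNA came from groups of 5 mice aged 3 months that received 5 daily oral doses of 20 µl, and cDNA was labelled with Cy5 or Cy3. The labels do not say how RNA from the mice of a group was combined.

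The deposited scanner files held spot brightness in both channels as linear intensity, with local background beside it, and the scanner software's log ratio of Cy5 over Cy3 on the log10 scale; both were written by Agilent Feature Extraction 11.5.1.1, per the file headers. The submitters' processing notes name Agilent Feature Extraction 10.10 and limma, with no step given for limma. The authors' deposited table of processed values held log2 ratios for 1646 genes of 22L, all of which matched a gene name on the array; its scale and direction were inferred from the scanner values, and its centring and filters are not given in the sources used here. The medians of the authors' deposited table were 0.05, -0.10, -0.05, -0.03 and -0.12 for the food medium, 4-species, bifidum, infantis and breve comparisons. Flag columns of the deposited files (well above background, saturated, outlier) were used as given. Each array file held 37603 spots, of which 36186 were not controls. Among them 7945 spots served 1664 genes of 22L, 8130 served 1707 genes of B. bifidum, 11380 served 2400 genes of B. infantis and 8697 served 1825 genes of B. breve; 34 further spots carried phage or plant sequences. The files pair the spots with locus identifiers and no product names, and no reference annotation was used here. For that reason the gene lists fixed before the data were examined could not be applied, no list was tested, and genes are given by identifier.

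Both arrays of every sample ran in opposite directions as scanned. Over the probes of the 4 genomes, the correlation of the scanner log ratio between array I and array II was -0.77, -0.66, -0.84, -0.71 and -0.84 in the food medium, 4-species, bifidum, infantis and breve comparisons, whereas the labels give a single dye orientation. The arrays were therefore treated as a dye swap, the sign of array I was turned, and each sample's arrays counted as 1 replicate. The direction is not settled by this. It is called likely here, on the basis that the dyes in the labels and the sign of the authors' deposited table both fit array II in all 5 samples. A well-above-background flag was read in the channel that holds a given RNA, which changes dye between arrays I and II.

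Intensities were background-corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50), then normalized within each array by loess weighted on 22L probes alone. Spots marked as outliers were left out and saturated spots were kept. A gene's value on an array was the median of its probes, and a sample's value the mean of its arrays. A gene was measured in a comparison if at least 50% of its probes were well above background in the same RNA on both arrays. Because a comparison had 1 sample, no p-value was computed for it. A gene was counted as higher or lower when its log2 ratio was at least 1 in size with the same sign on both arrays, and genes past that size with opposite signs were counted beside it as array noise. The SD given with a gene is that between the 2 arrays of a sample, which counted as 1 replicate. It includes any effect of the dyes, and whether both arrays held the same RNA extracts is not given.

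The 4 co-colonised comparisons share the RNA of mice given 22L alone. Their mean was tested against 0 with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg, adjusted p threshold 0.05) over genes measured in at least 3 of the 4. Such a test leaves out the spread of the shared control RNA. In a simulation of this fit over 648 genes with 200 changed, it recovered 95% of genes changed 2-fold and 100% of genes changed 4-fold, with 8 false calls. Those false calls are no error rate for the real data, where random deals of probes to genes, described below, called a median of 35.5 genes. Correlations between comparisons were taken across genes, which are not independent replicates, and set beside values simulated for comparisons that share only a control RNA.

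As a check of the gene values, probes were dealt to 22L genes at random 100 times and the counts repeated. Agreement between probes was measured by the intraclass correlation, the share of variance that lies between genes. Brightness was compared between genomes within bins of equal GC count 2 bases wide. With blastn 2.17.0, 859 of the 7945 probes of 22L matched a probe of another genome on the array over at least 50 identical bases of 60.

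The rule for named genes, fixed before the data were examined, took 2-fold genes with at least 3 probes (or all, if fewer) of one sign on each array, ordered by mean log2 ratio, and asked for a described product. Its product part could not be applied, so at most 2 identifiers per direction are named. Where a gene's probes were not well above background in one RNA on both arrays, or saturated in one RNA on both arrays, the fold is given as "at least". It was computed from separate channels after loess and Aquantile, with a dim probe raised to the lowest signal well above background on its array. Such a fold is for the mean of the 2 arrays, and the ratio on a single array may lie below it.

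Alternatives chosen before the data were examined were no background subtraction, the scanner log ratio, loess on all 4 genomes, median centring, no filter or a stricter filter on dim genes, the mean over probes, each array alone, removal of cross-matching probes, the authors' table and other size thresholds; for the mean over the consortia also 8 arrays with the sample as a random block, each consortium left out, the 3 pairs apart, and a trended robust fit. Restricting to genes with at least 5 probes, removing saturated spots, and the stricter filter for the mean over the consortia were chosen after seeing the data. Each comparison was on its own slide, so slide and comparison cannot be told apart. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.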

Results

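The data comprised 10 arrays from 5 comparisons of bifidobacterial RNA. B. adolescentis 22L, a strain of a common gut bacterium, was given to mice alone, with 1 of 3 other bifidobacteria (B. bifidum PRL2010, B. longum subsp. infantis ATCC15697 or B. breve 12L), or with all of them. One comparison set 22L in mice against 22L grown in a medium made with mouse food, which asks how the strain's transcripts differ between the gut and culture. The other 4 set co-colonised mice against mice given 22L alone, which asks how other bifidobacteria alter transcripts of 22L. Each comparison had n = 1 with 2 arrays, so no comparison has a replicate check. Directions are likely ones, since both arrays of each sample ran in opposite dye directions; with the sign turned, every higher count below becomes lower and the reverse.

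In mice against food medium, 81 of 793 measured genes of 22L differed 2-fold on both arrays, 41 higher and 40 lower in mice (40 higher and 41 lower with the sign turned). The strongest lower genes were 22L_0104, at a log2 ratio of -5.48 ± 0.57 (SD between arrays), and 22L_0293, at -4.60 ± 0.76. In mouse RNA only 1 of the 5 probes of 22L_0104 was well above background on each array, so the size of its ratio rests on signal near background. All 5 probes of each gene were lower on both arrays, and the probe values of 22L_0104 ranged from -6.16 to -3.37. Among higher genes, 22L_0852 was at least 66.5-fold higher in mice in the mean of its arrays. The SD between its arrays was 1.15 on the log2 scale, and array I alone gave a log2 ratio of 5.34, below that fold. Folds and SDs of this gene below are given likewise. It has 1 probe, which was saturated in mouse RNA on both arrays, and the authors' deposited table lists it at 0. The gene 22L_0533 had a log2 ratio of 2.59 ± 0.48 over 2 probes, of which 0 on array I and 1 on array II were well above background in food-medium RNA. Only 2 genes passed 2-fold with opposite signs on the 2 arrays. Measured genes correlated between arrays at r = 0.68, with a typical SD between arrays of 0.55 on the log2 scale against 0.87 across genes. The scanner log ratio gave 191 genes, 74.9% of them higher in mice against 50.6% here, and the stricter filter on dim genes left 18, with 16.7% higher.

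With all 4 species in mice against 22L alone, 32 of 804 measured genes differed 2-fold, 7 higher and 25 lower (25 higher and 7 lower with the sign turned). The gene 22L_1273, read by 1 probe, had a log2 ratio of 3.93 ± 2.5, and 22L_0738 had 2.27 ± 0.67. The 5 probes of 22L_0738 ranged from -0.01 to 4.63. On the lower side 22L_0852 was lower on both arrays, but no fold is given, since the arrays differ and its 1 probe was saturated in the 22L-alone RNA and, on array I, not well above background in the 4-species RNA. The gene 22L_1662 had a log2 ratio of -2.03 ± 0.82 over 3 probes, of which 1 on array I and 0 on array II were well above background in the 4-species RNA, so the size is not exact. No gene passed 2-fold with opposite signs on the arrays, and arrays correlated at r = 0.51 across genes. Array I alone gave 150 genes. The balance of directions turned under the stricter filter on dim genes, with 77.8% of 9 genes higher, and was even at 3-fold, with 50% of 8 genes higher.

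With B. bifidum, 25 of 611 measured genes differed 2-fold, 16 higher and 9 lower (9 higher and 16 lower with the sign turned). The gene 22L_1273 was at least 10.97-fold higher in the mean of its arrays (SD between arrays 1.03 on the log2 scale). On array II alone its log2 ratio was 2.72, which is below that fold. Its 1 probe was not well above background in 22L-alone RNA on either array. The gene 22L_0991 had a log2 ratio of 3.16 ± 1.52 over 2 probes, of which only 1 was well above background in 22L-alone RNA on each array. Lower genes included 22L_0852, at least 38.97-fold (SD 1.03), and 22L_1699, at -2.31 ± 0.22, whose 5 probes ranged from -2.98 to 1.89. On array II only 2 probes of 22L_1699 were well above background in the co-colonised RNA. With the mean over probes 22L_1699 was at -0.99, short of 2-fold. Under median centring 15.2% of the 2-fold genes were higher, against 64% here, and on array II alone 35.9%.

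With B. infantis, 27 of 706 measured genes differed 2-fold, 9 higher and 18 lower (18 higher and 9 lower with the sign turned). The gene 22L_0991 had a log2 ratio of 2.68 ± 0.32, but its 2 probes lay at 1.055 and 4.30 and only 1 of them was well above background in 22L-alone RNA on each array. The gene 22L_0606 had 2.13 ± 0.27, with 5 probes from -1.20 to 3.74. In 22L-alone RNA 4 of these were well above background on array I but only 1 on array II. Without probes that match another genome 22L_0606 was at 0.24, short of 2-fold. On the lower side 22L_0852 differed at least 31.3-fold (SD 0.31) and 22L_1662 had a log2 ratio of -3.32 ± 0.26 over 3 probes, from -3.75 to -0.69. Under median centring 67 genes passed and 89.5% of them were higher, so the balance of directions rests on the normalization.

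With B. breve, 71 of 853 measured genes differed 2-fold, 31 higher and 40 lower (40 higher and 31 lower with the sign turned). The stricter filter on dim genes left 34, with 58.8% higher against 43.7% here, so the balance of directions turned. The gene 22L_1689 had a log2 ratio of 2.69 ± 0.13, but its 5 probes ranged from -2.33 to 3.70, and the authors' deposited table lists it at 0.94. The gene 22L_0465 had 2.52 ± 0.47, with probes from -1.77 to 4.06. In 22L-alone RNA only 2 of its 5 probes were well above background on each array, and 2 of 5 of 22L_1689 on array II. Lower genes included 22L_0852, at least 34.7-fold (SD 1.18), and 22L_1662, at -3.27 ± 0.10 over 3 probes, from -3.54 to -1.87. Only 1 of the 3 probes was well above background in the co-colonised RNA on each array, so the size of this ratio rests on signal near background.

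**Figure D1:**
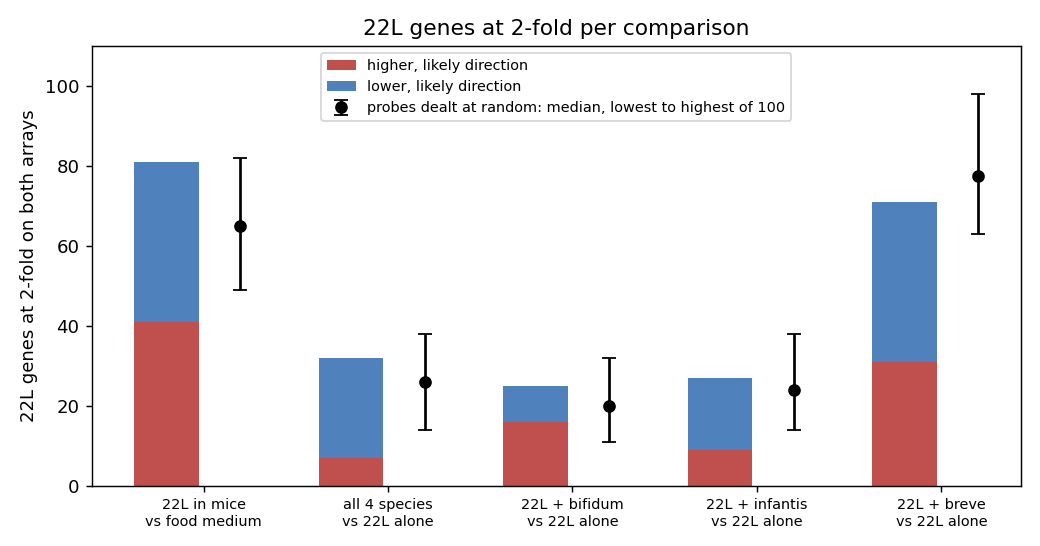
Bars show, for each of the 5 comparisons, the number of 22L genes at 2-fold on both arrays, split into higher and lower in the likely direction. Points and whiskers show the median and the lowest to highest count when probes were dealt to genes at random 100 times; the count of 81 in the food medium comparison lies near the top of its range of 49 to 82, and all 5 counts lie within their ranges.

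When probes were dealt to genes at random, similar numbers passed. The random deals gave a median of 65 genes for the food medium comparison, with a range of 49 to 82. Medians were 26, 20, 24 and 77.5 for the 4-species, bifidum, infantis and breve comparisons, against 32, 25, 27 and 71 observed. In 4 of 100 deals the food medium count was reached, and in 12, 14, 31 and 78 of 100 the counts of the other comparisons in that order.

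Over the 4 co-colonised comparisons together (n = 4), 35 of 648 measured genes passed limma's test at the adjusted threshold, all of them lower in co-colonised mice and with the same sign in all 4 samples (all higher with the sign turned). The gene 22L_0852 was lower in 4 of 4 samples (limma adjusted p = 3.1e-07). Its probe was saturated in the control RNA, so no mean ratio is given and the p rests on values limited by saturation. All 4 ratios share that control RNA, which is also the numerator of the food medium comparison. The 4 samples are therefore not independent replicates for this or any other gene of the test. The authors' deposited table lists 22L_0852 at exactly 0 in every comparison, so a test there could give no call. Whether that 0 is a missing value is not given. The gene 22L_1662 was also lower in 4 of 4 samples (limma adjusted p = 0.0069), with all 3 of its probes lower; no mean ratio is given, since most of its probes were not well above background in the 4-species and breve RNA. No gene was called higher at these settings, and 135 genes had an unadjusted p under the same threshold. Random deals of probes called a median of 35.5 genes, from 3 to 62. Their medians were 34 lower and 2 higher, so mostly lower calls also arose with probes dealt at random. With the mean over probes in place of the median 111 genes passed, 21 of them higher, and 16 of 167 were higher in the authors' deposited table, where all 1646 genes were tested with no filter on dim genes. Without the breve comparison 14 passed; leaving out the 4-species, bifidum or infantis comparison gave 15, 21 and 16.

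Between pairs of co-colonised comparisons the log2 ratios of measured 22L genes correlated at r = 0.45 to 0.51, with a mean of 0.48 over 6 pairs, against 0.50 simulated for comparisons that share only their control. Covariances ranged from 0.17 to 0.25, against 0.18 to 0.25 calculated with the shared control giving an equal part of the variance. This restates the correlation, since the calculated values come from the spread of the same log2 ratios. The food medium comparison, in which the same RNA of 22L in mice is the numerator, correlated with them at r = -0.46 to -0.38, against -0.50 simulated. The simulated 0.50 and -0.50 follow from giving every RNA the same variance and no array noise. The real share of the control RNA in the variance is not known. Summed over the 6 pairs, so that a gene shared by several pairs counts in each, there were 44 shared calls at 2-fold in the same direction and 0 in opposite directions. A simulation with only the control RNA shared gave 35.3 by the same sum, and independent lists would share 5.54. Summed likewise over the pairs of the food medium comparison with the 4 others, 46 shared calls were in opposite directions and 3 in the same, against 36.6 and 0.08 simulated with only that RNA shared. Of the 648 genes, 30.1% had one sign in all 4 comparisons, against 40.04% simulated with a shared control, again at equal variance, and 12.5% for independent values. The control RNA cannot be split, so part of any excess may come from it. Rank correlations were lower, at 0.28 to 0.41 between co-colonised comparisons.

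Probes designed on the other 3 genomes served as a check of which RNA each channel held. In the 22L culture grown in food medium, 32.8% of 22L probes were well above background (mean of 2 arrays), against 41.6% of B. bifidum, 33.7% of B. infantis and 29.6% of B. breve probes. In RNA of mice given 22L alone the shares were 48.0%, 58.8%, 51.3% and 47.0% over 10 readings. None of the 153 negative control spots passed in any reading, and 17.6% of the 34 phage or plant probes did in culture RNA. In co-colonised comparisons, probes of a genome that was given had a median log2 ratio of 0.0129 ± 0.0122 relative to 22L probes (mean ± SD over 6 genome and comparison pairs), against 0.0210 ± 0.0120 for 6 pairs in which the genome was not given. In the food medium comparison, where none of the 3 was given, it was 0.0433 ± 0.0379. The ranges overlapped, and no rise of a partner's probes in the co-colonised RNA was seen.

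**Figure D2:**
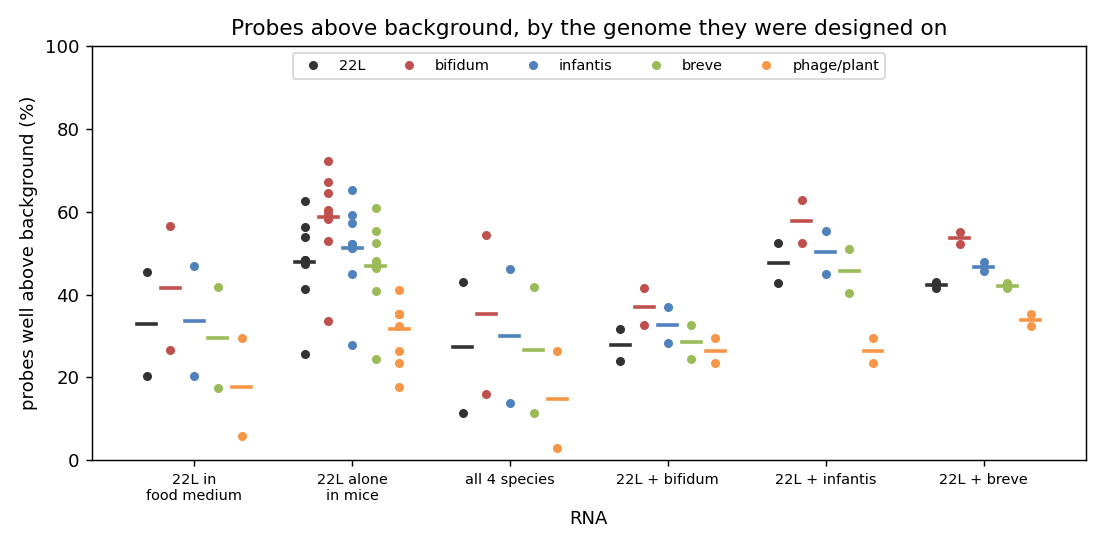
Each point is the percentage of probes well above background in one reading of an RNA on an array, by the genome the probes were designed on, and short lines are means. In RNA of 22L grown in food medium the means were 32.8% for 22L probes and 41.6% for B. bifidum probes.

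Probes of one 22L gene were also compared with one another. The intraclass correlation of their log2 ratios was 0.021, 0.0076, 0.0074, 0.0010 and -0.0064 in the food medium, 4-species, bifidum, infantis and breve comparisons, over 1646 or 1647 genes. Spots that carried the identical sequence at different places on the array had values of 0.96, 0.96, 0.98, 0.93 and 0.97. These were 350 to 356 repeated sequences from all 4 genomes, not from 22L alone. A gene's value is therefore a median over probes that differed from one another about as much as probes of different genes did.

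**Figure D3:**
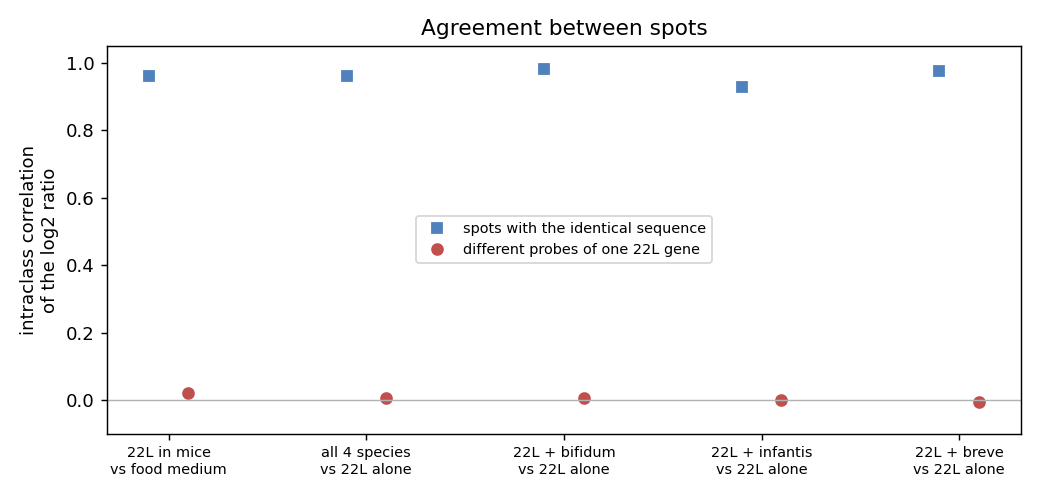
Each point is an intraclass correlation of the log2 ratio in one of the 5 comparisons, for spots with the identical sequence (squares) or for different probes of one 22L gene (circles). Identical sequences lie at 0.93 to 0.98, and different probes of a gene lie near 0, at 0.021 or below.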

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

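The tests in this part were chosen after the result was seen. Signal appeared on probes of genomes that were not in the culture. In RNA of 22L grown alone in food medium, 41.6% of B. bifidum, 33.7% of B. infantis and 29.6% of B. breve probes were well above background. This compares with 0 of the 153 negative control spots and 32.8% of 22L probes. Arrays I and II differed, at 20.3% and 45.4% for 22L and 26.7% and 56.6% for B. bifidum probes. Some such signal was possible by design, since 859 of the 7945 probes of 22L matched a probe of another genome.

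Different probes of one 22L gene disagreed in log2 ratio, as their intraclass correlation lay between -0.0064 and 0.021 in the 5 comparisons, while spots carrying the identical sequence reached 0.93 to 0.98. Noise of single spots is argued against by that lowest value of 0.93, and a wrong layout or wrong gene names by it together with the intraclass correlation of GC content within genes, 0.46. Hybridisation that does not follow transcripts of the inoculated strain is a candidate explanation. At equal GC count, the median of 22L probes differed from that of the other genomes by 0.0037 on the log2 scale in culture RNA, where 22L was the only strain grown. Only 32.8% of 22L probes were well above background there, so these medians lie among dim probes. The difference could miss 22L probes that were brighter, and it cannot decide the question. Such hybridisation would not cover the 6 genes whose 5 probes were all lower in mice than in food medium. What RNA or DNA bound the probes was not tested, and no biological explanation was tested.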

How the results depend on the processing

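No paired analysis was possible because each group has 1 sample. The food medium, 4-species, bifidum, infantis and breve counts at 2-fold (81, 32, 25, 27 and 71) were 191, 108, 134, 123 and 137 with the scanner log ratio, 238, 163, 123, 138 and 207 in the authors' deposited table, 18, 9, 10, 15 and 34 under the stricter filter, 173, 103, 56, 69 and 181 at 1.5-fold and 32, 8, 11, 9 and 17 at 3-fold. Without background subtraction the 4-species, bifidum, infantis and breve counts were 19, 38, 55 and 45. Median centring gave 55 for the 4-species and 67 for the infantis comparison. The mean over probes gave 56, 54 and 50 for the 4-species, bifidum and infantis comparisons, and genes with at least 5 probes, chosen after seeing the data, gave 17, 14 and 13. Removing probes that match another genome gave 49 for bifidum and 50 for infantis. Leave-one-out with each array alone gave 164 to 185, 58 to 150, 40 to 53, 40 to 150 and 141 to 149. The size threshold and stricter filter move counts by construction; otherwise the cause was not tested. The share of higher genes (50.6%, 21.9%, 64%, 33.3% and 43.7%) became 77.1%, 7.27%, 15.2%, 89.5% and 30.4% under median centring and 74.9%, 6.48%, 23.1%, 74.8% and 32.1% with the scanner log ratio; the stricter filter gave 16.7%, 77.8%, 80%, 26.7% and 58.8%, and array I alone gave 61.3% for infantis; median centring shifted the median of the measured genes by 0.25, -0.11, -0.34, 0.38 and -0.07, and the scanner log ratio by 0.24, -0.30, -0.34, 0.23 and -0.05. The 35 genes of the mean over the consortia became 20 with no filter, 111 with the mean over probes, 167 of 1646 unfiltered genes in the authors' deposited table, 12 for the 3 pairs apart and 4 under the stricter filter, added after seeing the data, which left 109 genes to test; genes called higher numbered 21 with the mean over probes, 16 in the authors' deposited table, 3 without cross-matching probes and 2 without background subtraction; leave-one-out over arrays and consortia ranged from 7 (array II alone) to 32. The mean correlation among co-colonised comparisons (0.48) was 0.36 by Spearman and 0.43 with the scanner log ratio; that of the food medium comparison with them (-0.41) was -0.31 and -0.34. The mean shift of probes of genomes given (0.0129) was -0.0162 with the scanner log ratio, -0.0121 with median centring, 0.0348 with the stricter filter and 0.0317 with the mean over probes. That of genomes not given over all 5 comparisons (0.0284) was 0.065 with the stricter filter. On array I and array II alone the shift was 0.0229 and 0.0028 for genomes given, and 0.0456 and 0.0112 for genomes not given. No value of a named gene changed sign, but 8 of 218 values in single comparisons fell short of 2-fold. With the authors' deposited values these were 22L_0852, at 0 in all 5 comparisons, and 22L_1689, at 0.94. The others were 22L_1699, at -0.99 with the mean over probes, and 22L_0606, at 0.24 without cross-matching probes. Many of the 218 could not differ: a filter on dim genes leaves a gene's value unchanged. The mean over probes does so for genes with 1 or 2 probes. Each array alone has the same sign by the rule for naming. The sign of each array was set to run the way of the authors' deposited table, so agreement in sign with that table was also likely in advance. Outside this count, 22L_0852 was also at 0 in the mean over the consortia with the authors' deposited values, where its call was lost. A slide block was not run, since each comparison was on its own slide. Signal over background limits the genes that could be measured.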

Other observations

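In the food medium comparison a small set of 22L genes stood apart from the rest. Of 1483 genes with 5 probes of different sequence, 6 had all 5 probes at least 2-fold lower in mice, that is, higher in the food medium culture, against at most 1 in 100 random deals of probes. They included 22L_0104 and 22L_0293. No gene had all 5 probes 2-fold higher in mice. In the breve comparison 1 gene had all 5 probes higher, against up to 2 in random deals, and in the other 3 comparisons 0 genes agreed in this way.

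The tests in this paragraph were chosen after the result was seen. The 35 genes called lower over the 4 consortia may reflect groups of unrelated probes: 54 of 100 random deals of probes to genes called as many, with 62 the highest. Turning the signs of whole samples gave 8 patterns, of which 1, the real one, reached 35 and the highest other gave 0. Such a number of patterns is too small for a share under the usual threshold. The 4 consortia also share a control RNA, so turning some signs breaks the agreement that this RNA gives. A low count in the other patterns was thus likely in advance, and the turns cannot decide the question.

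The correlation among co-colonised comparisons was weighed against 2 explanations, and the test of the shared RNA was chosen after the result was seen. The RNA of mice given 22L alone, common to all 4 comparisons, could account for it. Over 22L probes the observed covariance was on average 0.889 of the value calculated with that RNA giving an equal part of the variance. That value was not simulated but taken from the spread of the same log2 ratios. The ratio therefore restates the correlation over 22L probes and adds no separate evidence. For a response of 22L to the other species, the correlation over 22L probes should exceed that over probes of the other 3 genomes, and it did so by 0.0113 (0.445 against 0.433). This was under the bound of 0.1 set beforehand. However, probes of the other genomes were well above background about as often as 22L probes in culture RNA of 22L. They are therefore no control free of its signal, and a response cannot be told apart from the shared RNA here.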
